A study of Mus musculus with 8 samples.

How the data were processed

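RNA from 8 neurosphere cultures of mouse neural stem and progenitor cells was sequenced, each culture grown from the brain of 1 fetus at embryonic day 14.5. A neurosphere is a floating cluster of cells grown from dividing neural precursors. Genotype and litter were taken from the labels: 4 fetuses had the gene Kat7 deleted by a Cre recombinase under Nestin control, and 4 carried the same recombinase with Kat7 intact. Each genotype came from 3 litters, 6 litters in all, and no litter held both genotypes, so litter and genotype cannot be told apart. Intact replicates 1 and 2 were littermates, as were deleted replicates 3 and 4. Per the labels' protocols, column-purified total RNA was made into polyadenylated RNA libraries and read as 100 bp single-end reads.

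The authors deposited raw counts of reads per gene, as whole numbers for 27179 Entrez gene identifiers, with no normalization. Per the submitters' processing notes, CASAVA 1.8.2, featureCounts and the mouse build mm10 were used. The aligner, the featureCounts version and the strand setting were not given in the sources used here. Without a stated strand setting, reads of overlapping genes cannot be told apart, a limit for Igf2r with Airn and Nnat with Blcap, and near-identical copies leave ribosomal protein genes and Gstm1 uncertain. The exons removed by the deletion are not named in the sources used here either, so reads from exons that remain would still be counted as Kat7.

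Symbols and coordinates were taken from a RefSeq gene table of GRCm38.p6, the assembly also called mm10, by exact Entrez identifier. Of the identifiers, 25275 matched and 1904 did not, and the unmatched ones were kept in the tests without a symbol. A total of 4984 genes had 0 counts in every library. Library totals ran from 10687817 to 22444359 counts, at which 1 read was worth between 0.0436 and 0.0918 CPM (counts scaled to a common library size). No molecular identifiers are named in the labels, so the exact Poisson intervals given for single counts (95%) cover counting error only.

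Genes were tested with edgeR 4.0.16 in R 4.3.3. The steps were filterByExpr with a minimum count of 10, TMM normalization, robust dispersion estimates and the quasi-likelihood F test of deleted against intact, with 4 libraries a side and no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 13498 genes tested. Adjusted p-values of genes come from this test unless another is named. CPM values use TMM-scaled library sizes, and their errors are SDs over 4 libraries. Log2 fold changes are deleted minus intact. Their errors are approximate standard errors, the absolute log2 fold change over the square root of the test's F, so they restate that test. The fold changes use edgeR's prior count of 0.125. So small a prior hardly shrinks the fold change of a gene with a few reads in 1 genotype, which is loosely bounded. Log2 CPM values use a prior count of 2.

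The test, the alternatives, 45 gene lists and the rule for naming genes were fixed before the data were examined. Lists with 5 or more tested members, 38 of them, were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The rule named Kat7 and, among called genes with non-overlapping genotypes and at least 5 CPM in the higher one, the 10 with the largest rise, the 10 with the largest fall and the 5 with the smallest p in each direction. Bare gene models and sex-linked genes were left out of that part. From each list it named up to 4 called members by p, or the most abundant member where none was called. From the stem cell, neuron, astrocyte, oligodendrocyte and replication lists it added the pair of members with the highest level. The text gives a selection of these. Genes named in the closing section for the NRF2 and lysosome lists were chosen after their values were seen.

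Alternatives were other scalings, DESeq2 1.42.0, limma-voom with and without sample weights, litter as a random block, summed littermates, the replicate number as a block, other filters, a test against a fold of 1.2, sex-linked genes left out, and each library left out in turn. A planned covariate from Xist was not run, since Xist had 0 to 6 counts in every library. A further 5 came after the values were seen. These were a variance per genotype, the pair of deleted libraries with Kat7 reads left out, the pair with the highest mitochondrial share left out, dominant RNAs left out, and the mitochondrial share as a covariate.

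The procedure was tested on simulated counts for 13329 genes with the real means and library sizes, 4 libraries against 4. Of 200 genes changed by design, 29.6% of those changed 2-fold and 74.2% of those changed 4-fold were called with the right sign, and 5 unchanged genes were called. The planted set had an adjusted p of 3.7e-15, and 0 of 19 unchanged sets were called. Genes were drawn independently, with the same dispersion in both genotypes. In the real data the estimated correlation was 0.669 for the DNA replication and 0.756 for the G2/M list. The median SD of log2 CPM was 0.17 in the intact and 0.38 in the deleted genotype. The simulation therefore does not show how often unchanged lists or genes would be called in the real data. Libraries of a genotype were compared for duplicates, and the lowest chi-square per degree of freedom of any pair was 12.8, so none was a repeat of another.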

Results

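The comparison asks how gene expression in cultured fetal neural stem and progenitor cells differs when Kat7, which encodes a histone acetyltransferase of the MYST family also called HBO1, has been deleted. Counts were available for 4 Kat7 deleted and 4 Kat7 intact neurosphere cultures, each from a separate fetus. Totals for intact replicates 1 to 4 were 13403953, 15887434, 18905228 and 22444359 counts, and for deleted replicates 1 to 4 they were 18280518, 10687817, 17256191 and 13115339. The mitochondrial genome gave 18.95% to 23.5% of the counts of intact libraries. It gave 29.9%, 18.95%, 17.1% and 34.4% in deleted replicates 1 to 4. Most of this mitochondrial share was a single ribosomal RNA, mt-Rnr2. It took 17.6% to 21.7% of the counts in intact libraries and 27.3%, 17.6%, 15.4% and 30.4% in deleted replicates 1 to 4. The Y-linked gene Ddx3y stood at 89.6 to 169 CPM in all 8 libraries and Xist at 0 to 6 counts.

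Kat7 (Entrez 217127, chromosome 11, 95271853 to 95310246 in GRCm38) was lower in all 4 deleted libraries than in any intact one. Intact libraries held 85.8, 77.1, 81.0 and 92.1 CPM, a mean of 84.0 ± 6.46 (SD, n = 4). Deleted replicates 2 and 4 kept 4 reads and 1 read (exact 95% Poisson intervals 1.09 to 10.2 and 0.0253 to 5.57 counts), or 0.437% and 0.104% of the intact mean. Deleted replicate 1 kept 416 reads (31.4%) and deleted replicate 3 kept 253 (16.5%), so the deleted mean was 10.2 ± 12.6 CPM. An exact two-sided permutation test on log2 CPM gave p = 0.0286, the smallest that the 70 arrangements of 4 against 4 allow. That test treats littermates as independent. In the edgeR quasi-likelihood test the log2 fold change was -3.02 ± 1.10 with an adjusted p of 0.128, which missed the threshold. Over 26 alternatives the adjusted p ran from 0.000113 to 0.276 and the log2 fold change from -8.51 to -2.62, with 4 alternatives past the threshold. Of these, the lowest adjusted p and -8.51 came from leaving out deleted replicates 1 and 3. That pair was picked for its Kat7 reads, so this pass was fixed by the choice. Leaving out deleted replicate 1 gave -4.03 with an adjusted p of 0.0562.

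**Figure D1:**
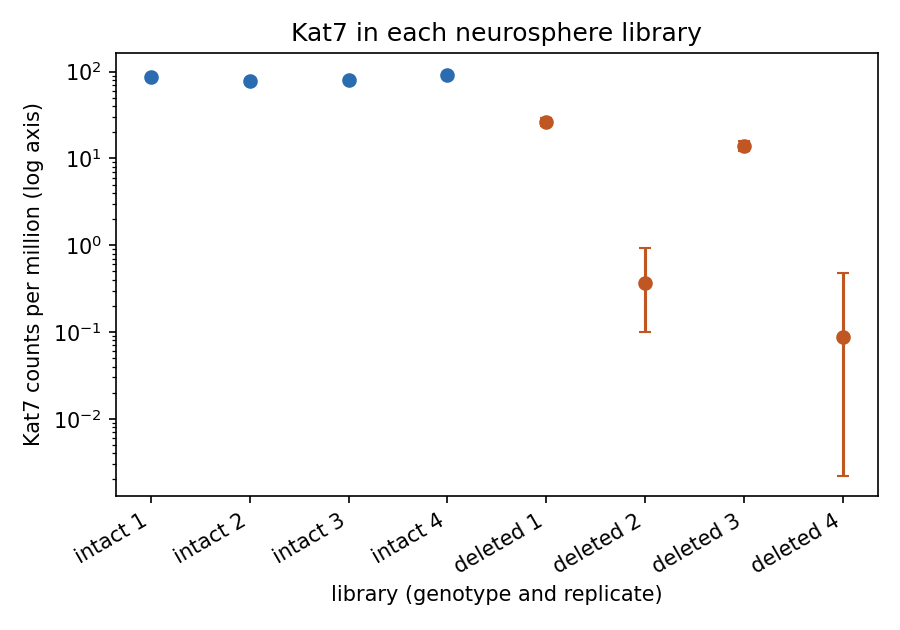
Kat7 in CPM on a log axis, 1 point per library, for the 4 intact and 4 deleted neurosphere cultures, with bars for the exact 95% Poisson interval of the count. Intact libraries lie at 77.1 to 92.1 CPM, deleted replicates 1 and 3 at 26.4 and 13.9, and deleted replicates 2 and 4 at 0.367 and 0.0870.

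The deleted libraries differed more among themselves than the intact ones did. Pairs of intact libraries correlated across genes at r = 0.978 to 0.990 and pairs of deleted libraries at 0.861 to 0.946, against 0.881 to 0.957 between genotypes (genes are not independent replicates). The median SD of log2 CPM was 0.17 within the intact and 0.38 within the deleted genotype, and 86.6% of genes had the larger SD in the deleted one. On the first principal component, with 45.9% of the variance, intact libraries lay between -40.2 and -37.7, and deleted replicates 1 to 4 at -16.0, 87.9, 14.4 and 70.2.

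**Figure D2:**
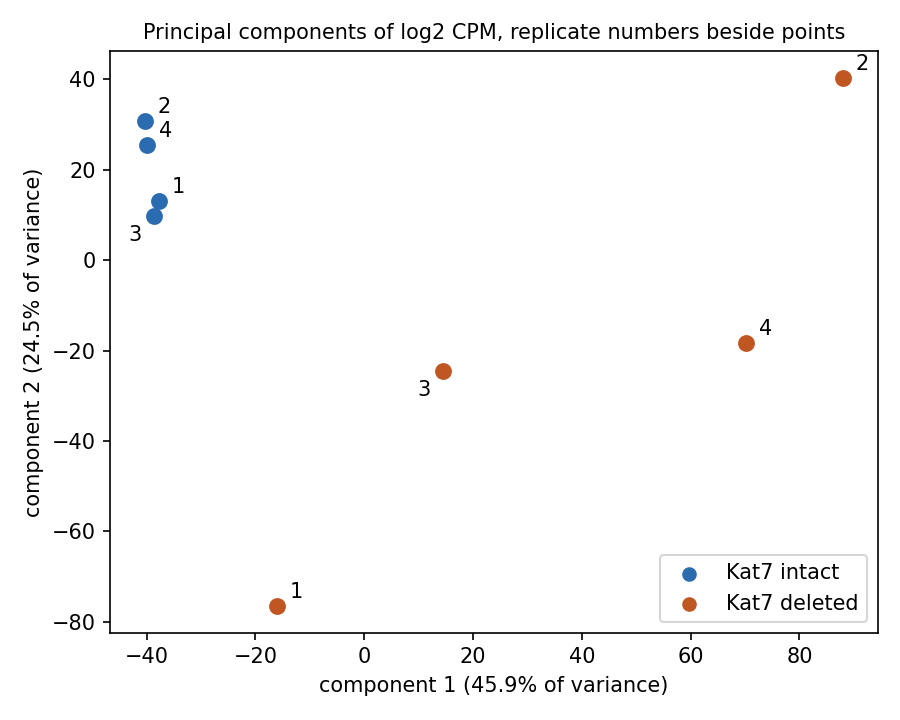
Principal components 1 and 2 of log2 CPM, 1 point per library, with 45.9% and 24.5% of the variance, blue for intact and orange for deleted, and the replicate number beside each point. The 4 intact libraries group together, and the 4 deleted libraries are spread along both axes.

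Slc7a11, the cystine transporter subunit that supplies glutathione synthesis, and Nqo1, a quinone reductase, rose in the Kat7 deleted cultures. Slc7a11 went from 48.7 ± 5.78 to 377 ± 112 CPM, 7.73-fold, and Nqo1 from 6.33 ± 1.49 to 48.5 ± 11.7 CPM, 7.66-fold (SD, n = 4). Tmsb10, an actin-binding thymosin, fell 4.48-fold from 68.6 ± 14.02 to 15.3 ± 1.38 CPM, and Bcat1, the cytosolic branched-chain aminotransferase, fell 10.1-fold from 39.1 ± 5.72 to 3.81 ± 1.79 CPM. Across the transcriptome, 1066 of 13498 tested genes (7.90%) were called, 688 higher and 378 lower. Of these 403 were at least 2-fold higher and 232 at least 2-fold lower. In all 3539 genes, the called ones included, had an unadjusted p under 0.05. All 4 deleted libraries lay above all 4 intact ones for 668 called genes and below them for 377. The genotypes did not overlap for 19.9% of all tested genes. Random assignment of 8 independent libraries gives 2.86%, but each litter held 1 genotype, so litter can add to the share too. With scaling by total counts alone, the median log2 fold change of all genes moved from 0.05 to -0.09 and the calls were 309 higher and 364 lower. Leaving out 1 intact library lowered the count to 250, 192, 261 and 189 for replicates 1 to 4. Without deleted replicate 1 or 2 it was 1721 or 2182. With litter as a random block 414 genes were called and with littermates summed 193, and 114 genes (68 higher, 46 lower) were called in all 27 settings.

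The calls with the smallest p also included Tmem176a, a membrane protein gene, with a log2 fold change of 1.97 ± 0.15, Plekho2 with 1.33 ± 0.11 and Fyco1, an adaptor for vesicle transport, with 1.54 ± 0.14. Adjusted p by edgeR was 0.00211 for Tmem176a, Slc7a11, Plekho2, Nqo1 and Tmsb10 and 0.00307 for Fyco1. On the lower side stood Brsk2, a kinase of neuronal polarity, at -1.63 ± 0.14, Tdrd7 at -1.29 ± 0.14 and Rundc3b at -4.24 ± 0.41, with adjusted p of 0.00307, 0.00483 and 0.00375. All of these kept their calls in all 27 settings.

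Among the largest falls, Epb41l3, a membrane skeleton protein, went from 11.8 ± 5.31 to 0.185 ± 0.173 CPM (log2 fold change -5.81 ± 0.66). Tenm3, a teneurin of synaptic adhesion, went from 37.2 ± 12.6 to 1.52 ± 1.27 CPM (-4.62 ± 0.57), and the immediate early gene Arc from 24.1 ± 18.2 to 1.41 ± 0.97 CPM (-4.04 ± 0.66). Bmerb1 fell by 4.55 ± 0.52 and Fxyd6 by 4.24 ± 0.65 on the log2 scale. Their edgeR adjusted p was 0.00485 for Epb41l3 and Bmerb1, 0.00711 for Tenm3, 0.0101 for Fxyd6 and 0.014 for Arc. They kept their calls with any 1 library left out, with values of -5.22 for Tenm3 without deleted replicate 4, -5.39 for Bmerb1 without deleted replicate 1, -4.90 for Fxyd6 without deleted replicate 3 and -3.41 for Arc without intact replicate 1. Of the 27 settings Arc was called in 23 and Epb41l3 in 26, the others in all.

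The largest rises were uneven between cultures. Ahnak, a giant scaffold protein, stood at 0.598 ± 0.272 CPM in intact libraries and at 2.03, 518, 15.4 and 10.3 CPM in deleted replicates 1 to 4. The smooth muscle actin gene Acta2 stood at 0.743 ± 0.0877 CPM against 1.90, 191, 6.92 and 107, and the matrix gene Thbs2 at 1.57 ± 0.70 against 2.66, 172, 14.3 and 132. Log2 fold changes were 7.86 ± 1.95, 6.67 ± 1.45 and 5.68 ± 1.24 with edgeR adjusted p of 0.0464, 0.0322 and 0.0329. Without deleted replicate 2 they were 3.97, 5.67 and 4.98. Gpnmb, a glycoprotein of lysosomes, stood at 0.327 ± 0.160 CPM in intact libraries and at 13.8, 0.643, 6.97 and 8.17 in deleted replicates 1 to 4. Deleted replicate 2 held 7 reads, against 11 in intact replicate 3 (0.538 CPM). The log2 fold change of Gpnmb was 4.48 ± 0.84 (edgeR adjusted p = 0.0195). All 4 calls were lost whichever intact library was left out, with adjusted p up to 0.141 for Ahnak without intact replicate 2, as was Ahnak's without deleted replicate 3 and those of Acta2 and Thbs2 without deleted replicate 4.

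**Figure D3:**
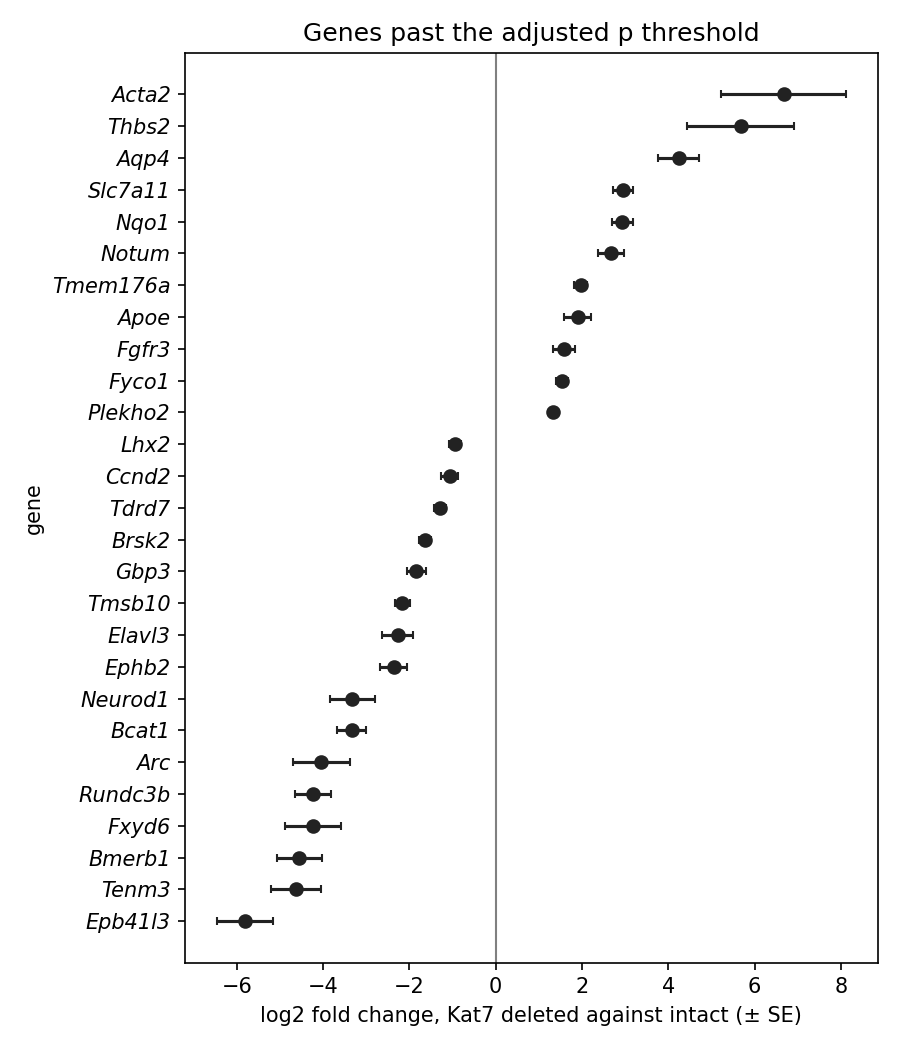
Log2 fold change of 27 called genes, Kat7 deleted against intact, from edgeR on 4 libraries against 4. Bars give the approximate standard error from the F test, with a line at 0. Acta2 at 6.67 and Epb41l3 at -5.81 mark the ends, and the bars are longest for Acta2 and Thbs2.

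Astrocyte markers were higher as a group in the Kat7 deleted cultures, with 18 of 19 tested members fitted above 0. Of the 19, 7 were called higher and 0 lower, and 11 were higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000488; adjusted p = 0.815 with an estimated correlation). No member was lower at an unadjusted p under 0.05 or by DESeq2 either. Aqp4, the astrocytic water channel, rose from 1.26 ± 0.442 to 24.0 ± 12.8 CPM (log2 fold change 4.24 ± 0.47, edgeR adjusted p = 0.00483). The 2 most abundant members were less clear. Acsbg1, an acyl-CoA synthetase, stood at 439 ± 104 and 519 ± 441 CPM (adjusted p = 0.813), and its log2 fold change of 0.24 turned to -0.51 without deleted replicate 1. Sparcl1, a secreted glycoprotein, rose by 2.67 ± 0.61 (adjusted p = 0.0376), with 295 CPM in deleted replicate 2 against 309 in intact replicate 3, and was called in 12 of the 27 settings. Fgfr3, a receptor of glial progenitors, rose from 17.9 ± 6.20 to 53.4 ± 7.81 CPM, and the lipoprotein gene Apoe from 8.41 ± 2.93 to 31.5 ± 9.34 CPM. The list lay 2.90, -0.01, 1.48 and 1.14 log2 units from the intact mean in deleted replicates 1 to 4. Its call ended without the pair of deleted libraries that hold Kat7 reads (adjusted p = 0.275) and without the pair with the highest mitochondrial share (0.194), the range over all settings reaching 0.275. Aqp4 kept its call throughout. Fgfr3 lost it without intact replicate 1 (adjusted p = 0.0508) and Apoe without intact replicate 1 or 4 (up to 0.0564). Clu, with a log2 fold change of 3.47 ± 0.72, lost it whichever intact library was left out (up to 0.101), as did Sparcl1, also without deleted replicate 3 or 4 (up to 0.115) and with a value of 2.00 without deleted replicate 1.

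Neuronal markers were lower as a group, though 6 of 16 tested members had a fitted fold change above 0 and 10 below. Of the 16, 2 were called lower and 0 higher, as many adjusted over the list alone, and camera gave an adjusted p of 0.0105, against 0.698 with an estimated correlation. With 1 member higher at an unadjusted p under 0.05 and 1 by DESeq2, fry, which tests whether a list moves one way, gave an adjusted p of 0.00198. That call was lost with littermates summed (0.0573) and with the replicate number as a block (0.13). Neurod1, a transcription factor of neuronal differentiation, fell from 3.68 ± 1.63 to 0.351 ± 0.222 CPM (log2 fold change -3.32 ± 0.52), and the RNA-binding protein gene Elavl3 from 6.97 ± 0.276 to 1.42 ± 0.663 CPM (-2.27 ± 0.36), with edgeR adjusted p of 0.0104 and 0.0116. Both kept their calls with any 1 library left out, but Neurod1 was called in 24 and Elavl3 in 26 of the 27 settings, each losing its call with littermates summed (0.0592 and 0.0751). Map2, the most abundant member, stood at 1030 ± 19.3 and 925 ± 139 CPM (adjusted p = 0.545). The list lay -0.78, -0.65, -0.95 and -1.12 log2 units from the intact mean in deleted replicates 1 to 4. Its camera call ended without the pair with Kat7 reads (adjusted p = 0.126) and the pair with the highest mitochondrial share (0.0721).

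Other lineage lists were not called by camera. The stem cell marker genes Nes and Vim, which encode intermediate filaments, stood at 1580 ± 258 and 1884 ± 209 CPM in intact and 1489 ± 564 and 1637 ± 510 CPM in deleted libraries (edgeR adjusted p = 0.879 and 0.619). Nes had no settled direction, at -0.08 with all libraries and 0.11 without deleted replicate 1, the range of its alternatives lying on both sides of 0. Of the 24 stem cell genes 1 was called, Zfp36l1, with a log2 fold change of 1.08 ± 0.25, and 0 adjusted over the list alone, where 4 were higher and 1 lower at an unadjusted p under 0.05 and 3 and 1 by DESeq2. In the oligodendrocyte lineage 2 of 14 were called lower, 3 adjusted over the list alone (camera adjusted p = 0.0713; adjusted p = 0.815 with an estimated correlation). These were Ugt8a, an enzyme of myelin lipid synthesis, at -4.17 ± 0.72 (-4.97 without deleted replicate 3), and Gpr17, a receptor of immature oligodendrocytes, at -3.21 ± 0.67 (-4.05 without deleted replicate 2). Olig2, a transcription factor of the lineage, stood at 565 ± 47.5 and 435 ± 203 CPM (adjusted p = 0.522). Intermediate progenitor genes had 2 of 10 lower, Sstr2 at -1.81 ± 0.42 and Elavl4 at -1.50 ± 0.37, and GABAergic lineage genes 2 of 6 higher, Dlx1 at 2.33 ± 0.53 and Sp9 at 1.94 ± 0.46. Foxj1, a regulator of motile cilia, rose by 1.21 ± 0.23 among 5 ependymal genes, and Lhx2 fell by 0.95 ± 0.14 among 17 forebrain genes. Adjusted over the list alone, 1 intermediate progenitor gene was higher and 2 lower, 3 GABAergic genes were higher, 2 ependymal genes were higher and 1 lower, and 1 forebrain gene was lower. Camera gave adjusted p of 0.939 for stem cell, 0.792 for intermediate progenitor, 0.576 for GABAergic, 0.842 for ependymal and 0.571 for forebrain genes. Lhx2 kept its call with any 1 library left out and lost it with littermates summed (adjusted p = 0.0643), while the other called genes here lost theirs without 1 or more intact libraries, with adjusted p up to 0.126 for Zfp36l1 without intact replicate 2. Sstr2 lost its call also without deleted replicate 1, 3 or 4, Gpr17 and Sp9 without 3 or 4, Zfp36l1 without 3, and Dlx1 and Elavl4 without 4.

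DNA replication genes lay lower as a group in Kat7 deleted cultures, deleted replicate 2 aside. The mean log2 fold change was -0.33 over 41 tested members, with 38 below 0 and 3 above, and camera gave an adjusted p of 2.23e-06, with adjusted p = 0.815 with an estimated correlation. A single member was called, Pola1, the catalytic subunit of DNA polymerase alpha, from 148 ± 11.2 to 89.4 ± 21.8 CPM (log2 fold change -0.73 ± 0.18, edgeR adjusted p = 0.0452). Adjusted over the list alone 0 were called, against 16 lower at an unadjusted p under 0.05 and 3 by DESeq2. Mcm6, a subunit of the replicative helicase, stood at 320 ± 15.5 and 214 ± 72.1 CPM (adjusted p = 0.149), and Rrm1 of ribonucleotide reductase at 482 ± 22.7 and 361 ± 126 (0.305).

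G1/S genes had 2 of 30 lower, as many adjusted over the list alone, with a mean log2 fold change of -0.42 (camera adjusted p = 1.27e-05; adjusted p = 0.815 with an estimated correlation). Cyclin D2, Ccnd2, fell 2.09-fold from 601 ± 67.7 to 288 ± 67.6 CPM (edgeR adjusted p = 0.0179), and its partner kinase gene Cdk6 fell from 4.09 ± 0.927 to 1.37 ± 0.578 CPM (0.0455). Among 36 G2/M genes edgeR called 0, with 6 lower at an unadjusted p under 0.05 and 0 by DESeq2, and the mean was -0.32 (camera adjusted p = 0.000119; adjusted p = 0.815 with an estimated correlation). Top2a, the mitotic topoisomerase, stood at 910 ± 52.6 and 725 ± 314 CPM (adjusted p = 0.515). Replication genes lay -0.77, 0.03, -0.16 and -0.61 log2 units from the intact mean in deleted replicates 1 to 4. For G1/S genes the values were -0.80, -0.13, -0.21 and -0.73. For G2/M genes they were -0.97, -0.10, 0.12 and -0.62, so deleted replicate 3 lay above the highest intact library (0.08). The mitochondrial share was high in deleted replicates 1 and 4. Without these libraries the camera adjusted p was 0.218 for replication, 0.218 for G1/S and 0.97 for G2/M, the highest of any setting. Pola1, Ccnd2 and Cdk6 each lost their calls without 1 or more intact libraries, with adjusted p up to 0.136, 0.0681 and 0.141, and Pola1 also without deleted replicate 1, 3 or 4 and Cdk6 without deleted replicate 3.

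Genes of the p53 response moved in both directions. Of 30 tested, 2 were called higher and 3 lower, as many adjusted over the list alone (camera adjusted p = 0.0273, lower; adjusted p = 0.815 with an estimated correlation). Ddit4l, an inhibitor of mTOR signalling, rose by 2.93 ± 0.63 on the log2 scale (2.30 without deleted replicate 4) and Sesn1 by 0.86 ± 0.17. Eda2r, a death receptor, fell by 0.83 ± 0.18 and the exonuclease gene Aen by 0.56 ± 0.13. In the DNA damage list 1 of 28 was called, the checkpoint kinase gene Chek1, from 52.0 ± 4.32 to 30.6 ± 6.16 CPM, also 1 adjusted over the list alone (camera adjusted p = 0.0421; adjusted p = 0.815 with an estimated correlation). The p53 list lay -0.54, -0.30, 0.14 and 0.11 log2 units from the intact mean in deleted replicates 1 to 4. Deleted replicates 3 and 4 thus lay above the highest intact library (0.07). The p53 camera call was lost without deleted replicate 1 (adjusted p = 0.45) or 2 (0.0789). The damage call was lost without intact replicate 4 (0.0869), deleted replicate 1 (0.45) or 4 (0.072). All 5 genes named here lost their calls whichever intact library was left out, with adjusted p up to 0.111 for Aen, and Aen and Chek1 also without deleted replicate 4 and Ddit4l without deleted replicate 3. Of 28 apoptosis genes 3 were called higher and 0 lower (camera adjusted p = 0.571), with 4 higher adjusted over the list alone, 3 lower at an unadjusted p under 0.05 and 1 lower by DESeq2.

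Wnt pathway genes moved apart. Notum, a secreted enzyme that inactivates Wnt proteins, rose from 1.03 ± 0.296 to 6.58 ± 1.38 CPM (log2 fold change 2.67 ± 0.30, edgeR adjusted p = 0.00483), while the secreted antagonists Sfrp1 and Sfrp2 fell by 3.78 ± 0.43 and 2.86 ± 0.52. In all 1 of 29 members was higher and 3 lower, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.849). Notch genes had 3 of 20 higher, among them the receptors Notch3 at 1.89 ± 0.41 and Notch4 at 4.28 ± 1.02, the latter 2.83 without deleted replicate 2, with 4 higher adjusted over the list alone (camera adjusted p = 0.0872). Fgfr1 rose from 171 ± 18.1 to 288 ± 27.9 CPM, and the neuregulin receptor gene Erbb4 fell from 8.76 ± 1.66 to 0.745 ± 0.692 CPM (-3.54 ± 0.74, or -4.15 without deleted replicate 1). They belong to 26 growth factor signalling genes with 2 higher and 1 lower, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.436). The single called member of 11 Hedgehog pathway genes, Foxf1, had 1, 1, 2 and 0 reads in intact and 19, 38, 27 and 25 in deleted replicates 1 to 4, also 1 adjusted over the list alone (camera adjusted p = 0.792). BMP and TGF-beta genes had 3 of 26 higher and 2 lower, or 9 and 3 adjusted over the list alone (0.26). Notum, Sfrp1 and Foxf1 kept their calls with any 1 library left out. Of the 27 settings, Sfrp1 was called in 26 and Notum and Foxf1 in all. The other genes named here lost theirs without 1 or more intact libraries, with adjusted p up to 0.133 for Notch4 without intact replicate 2, and Notch3 and Erbb4 also without deleted replicate 3 and Notch4 without deleted replicate 4.

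Camera put cell adhesion and axon guidance genes lower, with 34 of 59 tested members fitted below 0 and 25 above. Of the 59, 2 were called higher and 7 lower, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.00813; adjusted p = 0.815 with an estimated correlation). Ephb2, an ephrin receptor, fell from 14.1 ± 2.78 to 2.71 ± 1.05 CPM (log2 fold change -2.37 ± 0.31, edgeR adjusted p = 0.00711) and kept its call with any 1 library left out. Nrcam, a neuronal adhesion molecule, rose by 0.98 ± 0.17 and lost its call whichever intact library was left out (adjusted p up to 0.0702). Among 19 glutamate and GABA receptor genes edgeR called 0, with 1 higher and 1 lower at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma-voom, while camera put the list lower (adjusted p = 0.0134; adjusted p = 0.815 with an estimated correlation). In deleted replicates 1 to 4 the receptor list lay 0.54, -2.54, -0.75 and -2.47 log2 units from the intact mean and the adhesion list 0.02, -1.73, -0.38 and -1.84. The 2 libraries with the lowest values, deleted replicates 2 and 4, were also those with the least Kat7, at 0.437% and 0.104% of the intact mean. The mean log2 CPM of the 4 tested mesenchymal and pericyte markers was highest in the same 2 libraries, at 4.59 and 4.64. Of these markers Acta2 stood at 191 and 107 CPM there, against 1.90 and 6.92 in deleted replicates 1 and 3. The mean of so few members may thus rest on Acta2. Whether the falls follow Kat7 or these markers was not tested. Camera still called both lists without the pair that holds Kat7 reads. That left the 2 lowest deleted libraries, so the calls add no support. The calls of both lists ended without deleted replicate 2 (adjusted p = 0.103 for each) or 4 (0.0698 for receptors, 0.0649 for adhesion).

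Kcnj10, the inward rectifier potassium channel of astrocytes, rose from 0.620 ± 0.354 to 5.89 ± 2.81 CPM, and Ryr3, a ryanodine receptor, fell from 11.1 ± 7.98 to 1.27 ± 0.196 CPM. Of 24 potassium and sodium channel genes 3 were higher, also 3 adjusted over the list alone, and of 45 calcium handling genes 2 were higher and 2 lower, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.26 and 0.792). The extracellular matrix list had 5 of 50 higher and 1 lower, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.792). Sparc, a collagen-binding matrix protein, rose from 57.7 ± 8.58 to 162 ± 65.0 CPM, and the laminin gene Lama1 had 12, 11, 15 and 29 reads in intact and 1, 0, 2 and 0 in deleted libraries. Ryr3 kept its call with any 1 library left out but held it in 23 of the 27 settings, losing it with litter as a random block (adjusted p = 0.0885) and with littermates summed (0.0659) among others. Lama1 lost it without intact replicate 4 (adjusted p = 0.0526), with a value of -4.73 without deleted replicate 3 against -3.91 with all libraries. Kcnj10 lost it without intact replicate 1, 2 or 4 (up to 0.0626) and Sparc whichever intact library was left out (up to 0.072).

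Cholesterol biosynthesis genes rose as a group, with 1 of 25 called higher, also 1 adjusted over the list alone (camera adjusted p = 0.0029; adjusted p = 0.815 with an estimated correlation). The called member was Tm7sf2, a sterol reductase, from 24.1 ± 1.89 to 54.6 ± 18.7 CPM (edgeR adjusted p = 0.0197). The list was called by camera in all 24 settings, with an adjusted p up to 0.0475 without deleted replicate 4, while fry gave an adjusted p of 0.297. It lay 0.10, 0.16, 0.29 and 0.64 log2 units above the intact mean in deleted replicates 1 to 4. Intact replicate 3 lay at 0.14, above deleted replicate 1. Oxidative phosphorylation genes had 1 of 60 higher, Ndufa6 of complex I at 0.70 ± 0.18, and 0 adjusted over the list alone, against 11 higher at an unadjusted p under 0.05 and 1 by DESeq2 (camera adjusted p = 0.000488; adjusted p = 0.815 with an estimated correlation). That call ended without deleted replicate 1 (adjusted p = 0.187), without the pair with Kat7 reads (0.242) and without the pair with the highest mitochondrial share (0.906). Of 12 mitochondrially encoded genes edgeR called 0, with 8 higher at an unadjusted p under 0.05, 5 by DESeq2 and 8 adjusted over the list alone, and their mean log2 fold change was 1.19 (camera adjusted p = 0.00153; adjusted p = 0.815 with an estimated correlation). Without the high-share pair that call too was lost (0.218). Tm7sf2 and Ndufa6 lost their calls whichever intact library was left out, with adjusted p up to 0.0829 and 0.138, and Ndufa6 also without deleted replicate 1, 3 or 4.

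Ribosomal protein genes lay lower, with a mean log2 fold change of -0.24 over 74 members (camera adjusted p = 1.27e-05; adjusted p = 0.815 with an estimated correlation). The 1 called member, also 1 adjusted over the list alone, was Rpl22, from 269 ± 6.26 to 171 ± 22.5 CPM (edgeR adjusted p = 0.0218). The list lay -0.77, -0.09, -0.35 and 0.09 log2 units from the intact mean in deleted replicates 1 to 4, and its call ended without the pair that holds Kat7 reads (adjusted p = 0.958). Among 30 genes of the unfolded protein and integrated stress responses 2 were higher and 1 lower, as many adjusted over the list alone (camera adjusted p = 0.576). Besides Slc7a11 these were Nupr1, a stress-induced transcription regulator, at 2.12 ± 0.33, and the asparagine synthetase gene Asns, from a mean of 147 to one of 73.1 CPM (log2 standard error 0.21). Hypoxia and glycolysis genes had 2 of 30 higher, also 2 adjusted over the list alone (0.505), and among 24 immediate early and stress genes edgeR called 0, with 4 higher and 1 lower at an unadjusted p under 0.05 and 1 by DESeq2 (0.505). Rpl22 and Asns lost their calls whichever intact library was left out (adjusted p up to 0.0857 and 0.0912), Asns also without deleted replicate 3, and Nupr1 without intact replicate 2 (0.0501).

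Gbp3, an interferon-induced GTPase, fell 3.58-fold from 51.9 ± 10.9 CPM and was called in all 27 settings (log2 fold change -1.84 ± 0.22, edgeR adjusted p = 0.00558), while Ifitm3, an interferon-induced membrane protein, rose by 3.24 ± 0.69, or 3.86 without intact replicate 3. Of 19 interferon genes 3 were higher and 1 lower, and of 13 antigen presentation genes 1 was higher, or 7, 1 and 2 adjusted over the list alone (camera adjusted p = 0.198 and 0.231). Of the chromatin genes, the polycomb methyltransferase gene Ezh1 rose from 6.01 ± 0.464 to 16.9 ± 5.91 CPM, and Suz12, another polycomb subunit, fell from 112 ± 12.2 to 74.8 ± 8.50. They belong to 40 histone modifier genes with 3 higher and 1 lower, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.26). Jade2, a scaffold subunit of KAT7 complexes, rose from 4.18 ± 0.204 to 14.6 ± 6.49 CPM, the 1 called member of 13 KAT7 complex and MYST genes, also 1 adjusted over the list alone (0.939). Imprinted genes had 1 of 25 higher, Igf2r at 1.45 ± 0.25, and 2 lower, Usp29 at -2.10 ± 0.41 and Nnat at -2.06 ± 0.42, or 3 and 6 adjusted over the list alone (camera adjusted p = 0.792). Of 6 germline genes edgeR called 0, with 1 higher and 1 lower at an unadjusted p under 0.05 and 1 lower by DESeq2 (0.792). Gbp3 aside, the genes named here lost their calls without 1 or more intact libraries, with adjusted p up to 0.108 for Ifitm3 without intact replicate 2. Ifitm3, Suz12 and Nnat lost theirs also without deleted replicate 3, and Suz12 and Nnat without 4.

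**Figure D4:**
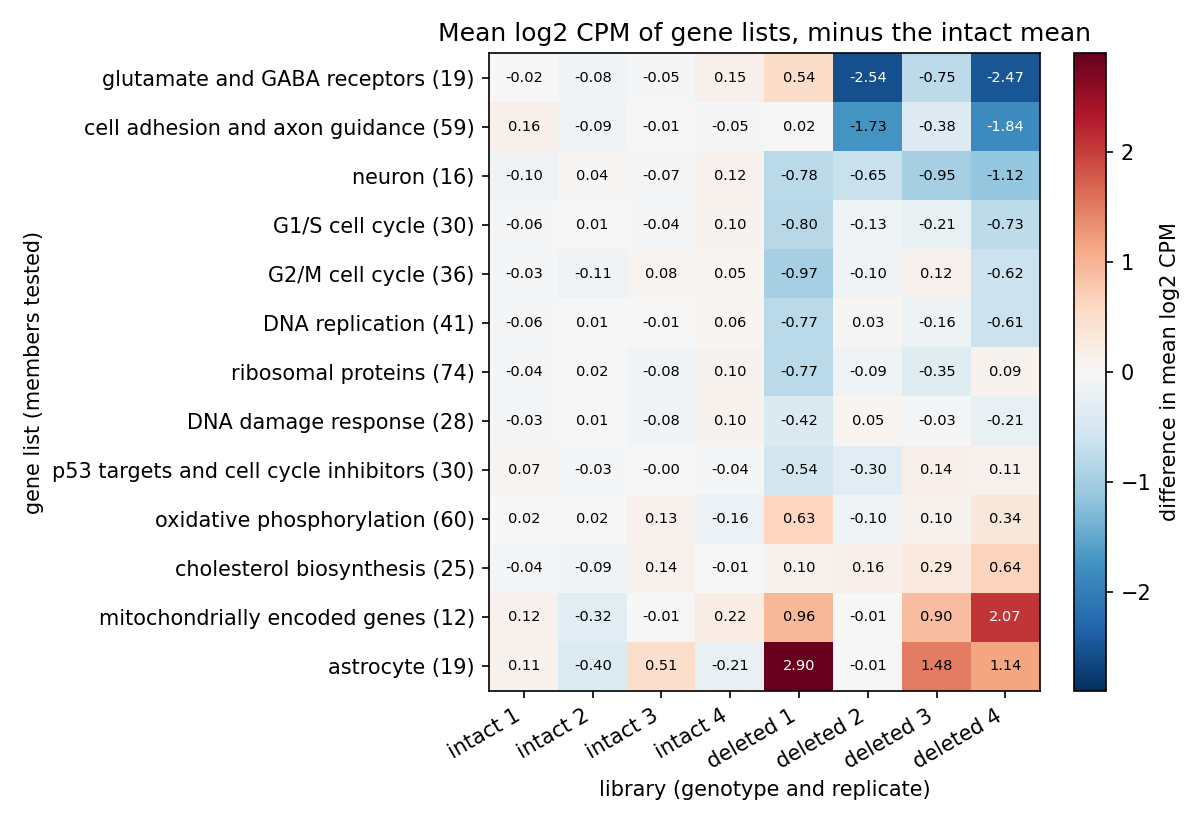
Mean log2 CPM of the members of the 13 called gene lists in each of the 8 libraries, minus the mean of the 4 intact libraries, as colour and as printed values, with the number of tested members beside each list name. The receptor list lies at -2.54 and -2.47 in deleted replicates 2 and 4, and the astrocyte list at 2.90 in deleted replicate 1 but -0.01 in deleted replicate 2.

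Few markers of non-neural cell types passed the count filter. Acta2 was the 1 called member of 4 tested mesenchymal and pericyte genes, with 2 adjusted over the list alone. The mean log2 CPM of the 4 was 2.21 to 2.77 in intact libraries and 3.28, 4.59, 3.58 and 4.64 in deleted replicates 1 to 4. Their mean log2 fold change was 2.08 and the median 1.02, so the mean leans on Acta2, at 6.67. Of 4 sex-linked genes 1 was called, the Y-linked Eif2s3y, from 52.4 ± 6.11 to 78.7 ± 12.2 CPM (edgeR adjusted p = 0.0465), and 3 were higher adjusted over the list alone. It lost its call whichever intact library was left out, and without deleted replicate 1 or 4 (adjusted p up to 0.146). Kdr, an endothelial receptor, had 10, 19, 14 and 19 reads in intact and 1, 1, 2 and 0 in deleted libraries, the 1 call among 5 endothelial genes, also 1 adjusted over the list alone (camera adjusted p = 0.697), and lost it without intact replicate 2 (adjusted p = 0.0501). Of choroid plexus, microglia, erythroid and neural crest markers 3, 3, 2 and 3 passed the count filter, and of posterior identity genes 4. None of these was called by edgeR, with 1 neural crest and 1 posterior gene lower at an unadjusted p under 0.05, and 1 neural crest gene lower by DESeq2 and 1 adjusted over the list alone. Over the 38 lists tested, camera called 4 higher and 9 lower, and 25 were not called. With an estimated correlation 0 were called and 1 had an unadjusted p under 0.05, and fry called 1, the neuron list. The mean, median and test differed in sign for 10 lists, 0 of them called.

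Littermates were compared with other fetuses of their genotype. Deviations from the mean of the genotype correlated across genes at r = -0.318 for the intact and -0.375 for the deleted pair of littermates. Pairs from different litters had a mean of -0.318 and a range from -0.661 to 0.159. Without any similarity such deviations correlate at about -0.333 in groups of 4, and both values lie near it. As a random block in limma, litter gave a correlation of 0.408. Over the 36 ways to pick 1 pair a genotype this ran from -0.789 to 0.411, and 2 reached the value of the littermates (exact p = 0.0556, a test chosen after the values were seen). Similarity within litters was thus not settled.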

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

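The tests of genes far below the intact level in deleted replicate 1 and of a swap of libraries were chosen after the Kat7 levels were seen. In 4 of 212 groups of 4 libraries (1.89%), 1 library stood apart from the other 3 by more than Dixon's 95% critical gap, where chance gives about 1 in 20. Dlx1 in the intact genotype was 0.179 CPM in replicate 2 against 0.391 to 0.436 in the others (gap ratio 0.8659 on the log2 scale with 0.1 CPM added). Cdk6 in the deleted genotype was 0.522 CPM in replicate 4 against 1.47 to 1.78 (0.8384). Usp29 in the deleted genotype was 0.174 CPM in replicate 4 against 0.551 to 0.634 (0.878). Eif2s3y in the deleted genotype was 60.6 CPM in replicate 3 against 82.6 to 87.5 (0.8439).

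Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many called genes as the genotypes did, the genotype split itself. It gave 1066, and the highest of the other splits gave 0. At an unadjusted p under 0.05 the values were 3539 and 1617. Ranking first of 35 is the most that this design can show. The other splits mix the genotypes, which widens the spread within groups, and some part littermates. The count thus argues against chance assignment of single libraries only, and litter, which is nested in genotype, stays open.

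Kat7 reads remained in deleted replicate 1 (31.4% of the intact mean) and replicate 3 (16.5%), and the 30 genes at under 2% of that mean in replicates 2 and 4 had a median of 105.2% in replicate 1 (95% interval 58.99 to 160.3) and 33.48% in replicate 3 (26.58 to 50.03). Both lie above the share that intact cells mixed with cells like those of replicates 2 and 4 would give, but the bound set was a lower one, and genes picked as low in 2 libraries tend to lie higher elsewhere, so the test decides nothing. Against unchanged intact cells at that share, 66 of 10381 genes in replicate 1 lay under 15.7% of the intact mean, where an intact library had at most 4, and in replicate 3 the counts were 12 under 8.27% and at most 2. A swap between genotypes is argued against by the lowest Kat7 level of an intact library, 91.78% of the mean. Deleted replicates 2 and 4 kept only 0.437% and 0.104% of the intact mean. If the deletion is the same in each culture, that argues against reads from exons that were not removed as the source. Open are incomplete recombination, which may leave cells with Kat7 copies whose other genes changed, and a true difference between fetuses or litters. Neither was tested.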

How the results depend on the processing

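The alternatives with a variance per genotype, with libraries left out in pairs, without dominant RNAs and with the mitochondrial covariate were chosen after the values were seen. The count of 1066 called genes (688 higher, 378 lower) stayed within 1.5 times under RLE and upper-quartile scaling, limma-voom, both filters, a variance per genotype, and with sex-linked genes or dominant RNAs left out (833 to 1067). It was 673 (309 higher, 364 lower) with total counts only, 525 (328, 197) against a fold of 1.2, and 674 (429, 245) with the mitochondrial covariate. It was 2203 (1317, 886) with DESeq2, 2283 (1291, 992) with sample quality weights, 2299 (1160, 1139) without the deleted libraries that hold Kat7 reads, and 1343 (753, 590) without the pair of high mitochondrial share. With litter as a random block 414 genes were called (232, 182), 409 of them shared, and with littermates summed 193 (106, 87), 188 shared. Leaving out 1 library gave 189 to 2182 calls, 102 to 1260 higher and 86 to 922 lower. The summed and left-out fits hold fewer samples; otherwise the cause was not tested.

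The replicate number as a block gave 319 calls (204, 115). The labels tie no number to a litter or day. Same-numbered libraries deviated together at r = 0.0961, 0.221, 0.110 and 0.331, and 2 of 4 matched their own number best, so a link between them stays open.

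The Kat7 level passed the threshold at -4.92 with limma-voom (adjusted p = 0.0426), -4.10 with quality weights (0.0347), -4.89 with a variance per genotype (0.0367) and -8.51 without the libraries that hold its reads (0.000113), over a range up to 0.276. The last of these left out libraries for their Kat7 level, so its pass was fixed by that choice. With 1 library left out the Kat7 log2 fold change ran from -4.03 to -2.62. The sign turned for uncalled genes: Nes to 0.033 with quality weights, 0.041 without the Kat7-read pair and -0.27 to 0.11 with 1 library left out, and Vim to 0.033 and Top2a to 0.10 without the high-mitochondrial pair. Acsbg1, at 0.24, turned to -0.16 with limma-voom, -0.096 with quality weights, -0.19 with the random block, -0.14 with the replicate block, -0.15 with a variance per genotype and -0.13 with the mitochondrial covariate. It was -0.83 without the Kat7-read pair, -0.65 without the high-mitochondrial pair, and -0.51 without deleted replicate 1 and 0.56 without 2. Camera called 7 lists without the Kat7-read pair and 5 without the high-mitochondrial pair, where its direction turned for G2/M, whose mean stayed below 0 (-0.00467), and for oxidative phosphorylation (-0.0234). The means of uncalled lists turned for ribosomal proteins (0.0154 without the Kat7-read pair) and p53 (0.0268 without deleted replicate 1). With an estimated correlation camera called 0, with 1 at an unadjusted p under 0.05. Fry called 1 list, but 0 with littermates summed or the replicate block, 5 without the Kat7-read pair and 2 with quality weights or without deleted replicate 4. Total counts only ended 3 list calls (p53, DNA damage, receptors), and quality weights and the mitochondrial covariate 2 each (p53, DNA damage). Of the named genes, 47 lost their calls with littermates summed, 33 with the random block, 36 with the replicate block and 20 with the mitochondrial covariate, in an unchanged direction. The cause was not tested. The Xist covariate was not run. DESeq2 and the fold test gave no list tests, and the random block gave fry only. Depth limits genes with a few reads, where 1 read is worth up to 0.0918 CPM.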

Other observations

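The lists of NRF2 targets and lysosome genes were made after the gene table was seen, as were the tests of both against the mitochondrial share. NRF2 is the transcription factor of the response to oxidants. Of 32 tested NRF2 target genes, 12 were called higher and 1 lower in the Kat7 deleted cultures, or 16 and 1 adjusted over the list alone, with a mean log2 fold change of 1.07 (camera adjusted p = 1.61e-10 over both lists; adjusted p = 0.0874 with an estimated correlation). Besides Slc7a11 and Nqo1, Gstm1 of glutathione conjugation rose by 2.57 ± 0.32, ferritin heavy chain, Fth1, by 1.89 ± 0.26 and heme oxygenase, Hmox1, by 1.69 ± 0.27 on the log2 scale, while the thioredoxin reductase gene Txnrd1 fell by 0.55 ± 0.11 (edgeR adjusted p = 0.00692, 0.00776, 0.0124 and 0.0228). How reads shared by Gstm1 and its near-identical neighbours were counted is not given, so its level stays uncertain. The neighbour Gstm2 was counted apart, at 0.142 CPM in intact and 1.89 CPM in deleted libraries, against 31.1 and 184 CPM for Gstm1. Of 67 lysosome genes 23 were called, each of them higher, and 33 adjusted over the list alone, with a mean of 0.56 (camera adjusted p = 4.84e-13; adjusted p = 0.092 with an estimated correlation). Among them were the sulfatases Galns at 1.47 ± 0.14 and Arsa at 1.83 ± 0.20, the hexosaminidase Hexa at 1.30 ± 0.20 and the protease Ctsb at 0.87 ± 0.19. The list lay 0.752, 0.338, 0.404 and 0.542 log2 units above the intact mean in deleted replicates 1 to 4. It was highest in replicates 1 and 4, which have the high mitochondrial share, and astrocyte markers lay 2.90, -0.01, 1.48 and 1.14 from the intact mean. Hmox1 lost its call without intact replicate 2 or 4 (adjusted p up to 0.0615) and Txnrd1 and Ctsb whichever intact library was left out (up to 0.0935 and 0.111), Ctsb also without deleted replicate 4.

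Deletion of Kat7 may go with a raised oxidant response and lysosome program, as a hypothesis found and tested on the same libraries. Without the genes that drew attention, camera from limma gave adjusted p = 8.79e-06 for NRF2 targets and adjusted p = 2.74e-11 for lysosome genes, adjusted over both lists, so those genes alone do not carry the rise. With an estimated correlation the adjusted p was 0.115 for both, and fry gave an adjusted p of 0.0103 for both. The NRF2 list lay 1.32, 0.759, 0.739 and 1.17 log2 units above the intact mean in deleted replicates 1 to 4, and at most 0.118 in an intact library, against 0.111 for lysosome genes. The lower value of replicates 2 and 3, whose mitochondrial share was low, was 0.739 for NRF2 targets and 0.338 for lysosome genes. This argues against the share of counts, mostly mt-Rnr2, as the whole cause. The list of mitochondrially encoded genes, however, lay 0.957, -0.009, 0.895 and 2.07 log2 units from the intact mean in deleted replicates 1 to 4. Only replicate 2, at 0.759 and 0.338, was low by both measures. For mitochondrial transcripts at large the question thus rests on 1 library, and litter and culture conditions stay open.

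The lower replication and cell cycle lists could follow the RNA composition of the libraries. With the mitochondrial share as a covariate the mean log2 fold change of the 107 members was -0.23, against -0.35 without it, and the camera adjusted p was 0.000201, 0.000998 and 0.0128 for replication, G1/S and G2/M. With an estimated correlation camera called 0 lists in that fit, so these p-values decide little. The mean that remained argues against a linear trend with the share as the whole cause. Without deleted replicates 1 and 4, however, the mean was -0.08 and the camera adjusted p 0.218, 0.218 and 0.97, the highest of all settings. The share is thus not settled as a cause. A slower cycle in those cultures and a difference in their state at harvest remain open and were not tested.

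Alleles of another strain linked to Kat7 were looked for through its neighbours. Within 5 Mb, 9 of 89 tested genes were called (10.1%) against 7.88% elsewhere (Fisher's exact p = 0.427, odds ratio 1.31, 95% interval 0.578 to 2.63). An odds ratio of up to 2.63 lies within that interval, so the p alone, set as the bound against linkage, was too broad and the question stays open.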
